A study of Mus musculus with 13 samples.

How the data were processed

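Total RNA of sorted spinal cord cells was purified with TRIZOL, treated with DNase, cleaned on columns and turned into libraries with the NuGEN RNA-Seq V2 kit, per the labels' protocols. Whether the libraries keep strand is not stated in the sources used here. The 13 samples were grouped by cell type and genotype from their labels, and the labels also gave the age (postnatal day 9 or 12). Per the submitters' processing notes, FastQC, TopHat2 2.0.11, Bowtie2 2.2.3, HTSeq 0.6.1p1, DESeq2, Cufflinks and Cuffnorm were used with build GRCm38. The settings and the annotation are not given in the sources used here.

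The authors deposited a table of FPKM for 39171 genes in the 13 libraries, scaled between libraries by a method that is not stated. The sums of FPKM differ between libraries. Per the file headers, the authors also deposited a table for each cell type with the normalised signal (mean normalised counts) of each genotype. Those tables give log2 fold changes of WT over KO, per the file headers, with and without shrinkage. They also hold the p-value and adjusted p of each gene, per the file headers, and list only genes with an adjusted p under 0.05. Per the file headers, the authors' columns carry the names that DESeq2 writes, and the direction was checked against the means of each genotype. The deposited FPKM are not counts, so no count test was run on them. Its lowest values are stepped, which gave the depth of each library relative to KO microglia 2 (KO microglia 77.8%, 100% and 85.5%; WT microglia 84.4%, 79.2% and 69.9%; KO astrocytes 46.3%, 60.4%, 63.4% and 40.1%; WT astrocytes 49.5%, 34.1% and 54.6%). The absolute depth is unknown, and no counting interval was computed. A shallower library gives noisier low values, which bears more on the astrocytes.

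Of the identifiers, 37605 (96.0%) were found in the GENCODE annotation of the mouse, release 21, on GRCm38, which supplied symbols, coordinates, gene types and exonic lengths. This replaced 27 symbols that had been turned into dates and filled in genes without a symbol (16252) where it held them. The table holds 8898 genes at 0 in every library and 5697 small RNA genes.

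Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided) on log2(FPKM + 1). Genes with a mean FPKM of at least 1 over the fitted libraries were kept, with Il33 kept in any case, and calls needed a Benjamini-Hochberg adjusted p under 0.05. Differences on this scale understate the change of low genes. Microglia were fitted alone (3 KO, 3 WT), astrocytes alone with age as a covariate (4 KO, 3 WT), and the interaction and the comparison of WT cell types in a fit of all 13 libraries with age as a covariate. Il33, Il1rl1 and Nfkbia were also tested on FPKM with an exact two-sided permutation test. FPKM are given as mean ± SD, except where libraries were listed at exactly 0.

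The 34 gene lists, the rule for named genes, the tests and the first group of alternatives given here were fixed before the data were examined. The lists cover NF-kB targets and pathway, IL-1 family genes, phagocytosis, complement, lysosome, microglial states, interferon response, antigen presentation, cell cycle, dissociation-induced genes, cholesterol synthesis, astrocyte functions, genes near Il33, markers of the cell types a sort could hold, and lists of sample quality. Lists with at least 5 tested members were tested with limma's camera, with an inter-gene correlation preset at 0.01 and, as an alternative, estimated from the data, and adjusted over the lists. In each list, members were also counted adjusted over the list alone and over all genes. Some markers stand in more than 1 list, namely Stab1 also among the phagocytosis genes, Cd44 also among the reactive astrocyte genes and Vcan among both monocyte and oligodendrocyte precursor markers. Of the border macrophage markers 12, of the monocyte markers 9 and of the neutrophil markers 11 passed the filter in microglia.

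The rule for named genes takes Il33, Il1rl1 and Il1rap, and per direction the 6 genes with the largest difference among those past the threshold whose groups do not overlap and whose higher group has a mean of at least 2 FPKM. For the interaction it takes the 3 largest per direction with no condition on overlap. Where fewer than 3 passed in a direction, it takes the 3 with the smallest p. It adds the 2 members with the smallest p of each list that was called or had a member past the threshold (up to 4 where 4 or more passed in a pathway list), and the 4 genes with the smallest adjusted p per direction in the authors' deposited results for each cell type, or all genes where there are 12 or fewer. For the cell types it takes the first 4 astrocyte and microglia markers and the 2 most abundant markers of any other list above 1% of the level of the population's own markers. Of the cell type markers that this rule takes, 2 are not reported here. Pseudogenes and called gene models known only by an identifier or a Gm number were not named by the rule. Other genes named from a list are members that passed adjusted over the list alone.

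The fits were tested on simulated data with 200 changed genes, 100 for each of 2 sizes. In microglia limma recovered 46% of genes changed by a log2 difference of 2 and 0% of those changed by 1, in astrocytes 47% and 5%, for the interaction 37% and 1%, and for the cell types 63% and 10%, with 2 to 5 calls among the unchanged genes. A list whose members were all shifted by −0.5 was found by camera in microglia (adjusted p = 1.56e-13) and astrocytes (0.0127), and with an estimated correlation in neither (0.0586 and 0.890). It was the NF-kB list, whose estimated correlation in the real data was 0.107 in microglia and −0.044 in astrocytes. The simulated noise was independent between genes, so this does not test camera where genes move together.

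The alternatives fixed at the start were a pseudocount of 0.1, no filter and a filter at 5 FPKM, median-ratio scaling, quantile normalisation, array weights, an adjusted p under 0.1, each library left out in turn, the replicate number as a block, all libraries in one fit, no age term and day 12 libraries alone. Alternatives added after the data were seen were a fit of protein-coding and long non-coding genes only, by gene type, leaving out genes listed at 0 in any fitted library, a sex covariate from Xist or Ddx3y, removal of a trend with GC content and exonic length, lists without shared members, the test of lists in the authors' tables, the test of lists on the interaction, the same test among genes with a mean of at least 1 FPKM in both cell types, and the count of splits by age. Work outside R used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R used version 1.17.8 of the package data.table.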

Results

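RNA sequencing libraries were made from 2 cell types sorted by flow cytometry from the spinal cord of young mice. Astrocytes were sorted by green fluorescent protein under the control of the astrocyte gene Aldh1l1, and microglia, the resident macrophages of the cord, by the surface protein CD11b. The mice either lacked functional Il33 (KO) or were WT littermates. Il33 encodes interleukin-33, a cytokine of the IL-1 family that signals through a receptor made of the products of Il1rl1 and Il1rap. The 13 libraries fell into 4 groups, with 4 KO and 3 WT astrocyte libraries and 3 KO and 3 WT microglia libraries. All microglia were taken at postnatal day 12. Among the astrocytes, KO library 2 and WT library 3 were taken at day 9 and the others at day 12. The libraries of a group are biological replicates, per the series' design text. Values were FPKM, fragment counts scaled to transcript length and library depth. The most abundant gene took 11.6% to 38.9% of the summed FPKM of a library. The number of reads is unknown. Steps between the lowest values gave only the depth of each library relative to KO microglia 2, which was 69.9% to 100% for the microglia and 34.1% to 63.4% for the astrocytes. The lowest correlation between 2 libraries of a group on the log2(FPKM + 1) scale was 0.760 in WT microglia, for libraries 1 and 3, and 0.867 in WT astrocytes, for libraries 2 and 3.

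Of the 2 sorted populations, the targeted gene Il33 (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718, GRCm38) was found mainly in WT astrocytes. It was nearly absent from KO astrocytes. The WT astrocyte libraries held 96.3, 113 and 108 FPKM, a mean of 106 ± 8.51 (SD, n = 3). The KO astrocyte libraries held 2.28, 2.05, 0.424 and 0.733 FPKM, a mean of 1.37 ± 0.931 (SD, n = 4), so that the WT mean was 77.0 times the KO mean. The exact two-sided permutation test of these values gave p = 0.0286, the smallest p that 4 against 3 libraries allow. The WT microglia libraries held 0.299, 0 and 1.26 FPKM and the KO microglia libraries 0.136, 0.00739 and 0 FPKM (exact permutation p = 0.4, where 0.1 is the smallest possible). The receptor gene Il1rl1 (chromosome 1, 40429570 to 40465415) had the opposite distribution. It stood at 7.08 ± 2.06 FPKM in WT microglia (SD, n = 3) and 7.47 ± 4.52 in KO microglia (SD, n = 3; exact permutation p = 0.9), and no astrocyte library reached 0.1 FPKM (exact permutation p = 0.543 for KO against WT). The co-receptor gene Il1rap was found in both cell types, at 1.92 ± 0.119 FPKM in WT microglia and 3.20 ± 0.479 in KO microglia (limma log2 difference 0.52, SE 0.22, adjusted p = 0.595).

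**Figure D1:**
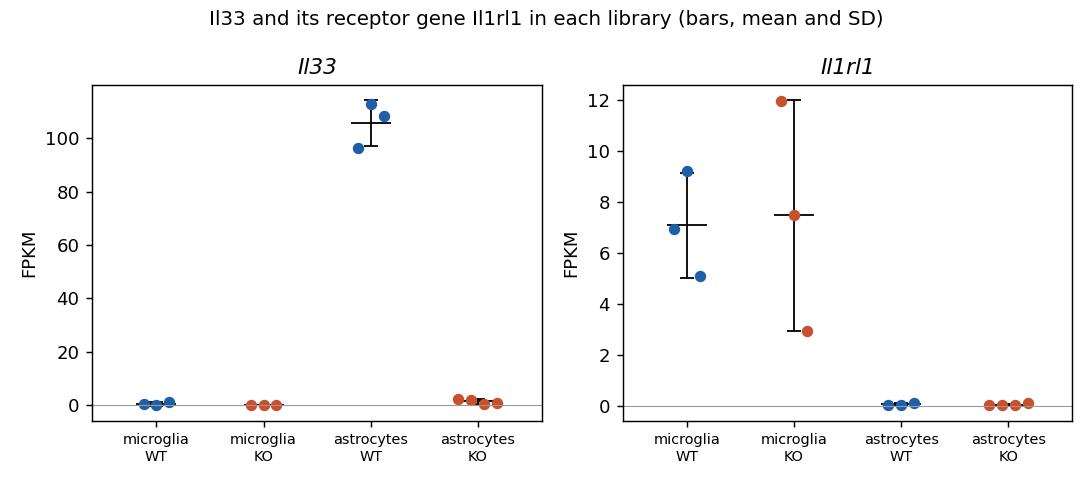
FPKM of Il33 and of its receptor gene Il1rl1 in each library of the 4 groups, with 1 point per library and bars for the mean and SD. Il33 lies between 96.3 and 113 FPKM in the 3 WT astrocyte libraries and at 2.28 or below in the 4 KO astrocyte libraries, while Il1rl1 is above 2 FPKM in the 6 microglia libraries and under 0.1 in all 7 astrocyte libraries.

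The comparison of KO with WT microglia asked which microglial transcripts differ when the cord lacks interleukin-33. Nfkbia, the gene of the inhibitor that NF-kB induces to limit its own activity (ENSMUSG00000021025; chromosome 12, 55489410 to 55492647), fell from 183 ± 32.0 FPKM in WT (SD, n = 3) to 31.9 ± 4.60 in KO (SD, n = 3). Other transcripts that NF-kB induces fell when adjusted over their list alone. Among them were the chemokine genes Cxcl2 (29.1 to 6.54 FPKM) and Cxcl10 (83.6 to 20.1; it overlaps Art3 on the other strand and is uncertain), the cytokine gene Tnf (66.6 to 22.5) and the feedback inhibitor gene Tnfaip3 (61.1 to 21.3). Genes of phagocytosis, complement, lysosomes and microglial identity did not pass the test, as single genes or as lists. In simulated data the fit found 0% of genes changed by a log2 difference of 1 and 46% of those changed by 2. Nfkbia differed by −2.48 on the log2(FPKM + 1) scale (SE 0.19, limma adjusted p = 0.0236) and lay lower in all 3 KO libraries than in any WT library (exact permutation p = 0.1, the smallest possible). In astrocytes Nfkbia stood at 30.4 ± 12.2 FPKM in WT and 17.5 ± 0.820 in KO (exact permutation p = 0.0857).

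As a group, the 39 tested NF-kB targets and pathway genes were lower in KO microglia, with a median log2 difference of −0.54 (camera adjusted p = 6.37e-10). The adjusted p was 0.586 with an estimated correlation between the genes. Adjusted over the list alone, 12 members fell, 1 rose and 26 did not pass, while over all genes tested only Nfkbia passed. The members that fell included Nfkbiz (62.5 to 28.9 FPKM), a nuclear regulator of NF-kB, Gadd45b (21.4 to 4.90), Cd83 (139.7 to 66.0), Ier3 (175 to 87.6), the anti-apoptotic Birc3 (59.0 to 27.9) and Bcl2a1b (33.1 to 21.1), and Csf1 (46.4 to 24.9), a growth factor for macrophages. The member that rose was Tnip1, which encodes a partner of the product of Tnfaip3 (3.56 to 7.11 FPKM). In each library, the median NF-kB member relative to its mean over the 6 libraries was −0.22, −0.31 and −0.21 in KO and 0.25, 0.11 and 0.53 in WT, and without WT library 3 the difference of the list was −0.32.

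**Figure D2:**
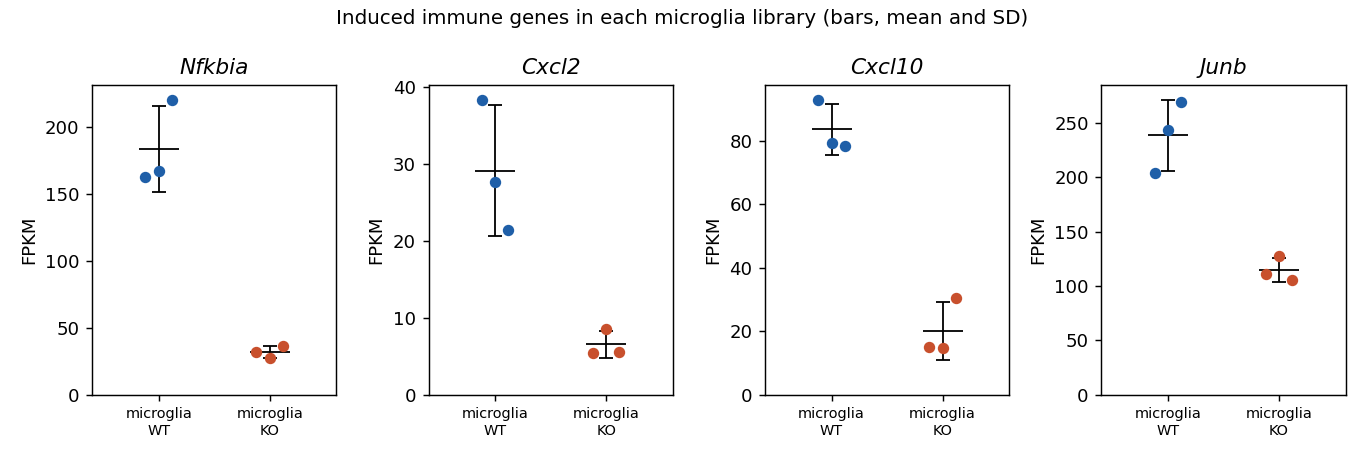
FPKM of the NF-kB targets Nfkbia, Cxcl2 and Cxcl10 and of the dissociation-induced gene Junb in each of the 6 microglia libraries, KO beside WT. Each library is 1 point, and bars give the mean and SD. For Nfkbia the KO libraries lie between 27.3 and 36.5 FPKM and the WT libraries between 163 and 220.3 FPKM.

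The list of immediate-early and heat-shock genes, which are induced when tissue is dissociated, was lower in the same KO libraries (34 members, median −0.34, camera adjusted p = 0.000267). The adjusted p was 0.586 with an estimated correlation. Adjusted over the list alone, 9 fell and 1 rose, and none of these was a heat-shock gene. Over all genes 0 passed in limma, with 12 members at an unadjusted p under 0.05. Junb, which overlaps Prdx2 on the other strand and is uncertain, fell from 239 to 115 FPKM, Dusp1, which encodes a phosphatase of MAP kinases, from 662 to 329, and Zfp36, which encodes a protein that destabilises cytokine messages, from 2290.4 to 1252, while the transcription factor gene Egr3 rose from 0.474 to 5.34. Ier3 and Gadd45b belong to both lists. Without these 2 genes the NF-kB list kept a median of −0.49 (camera adjusted p = 1.95e-08; adjusted p = 0.742 with an estimated correlation).

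Lists of markers of other cells also differed by genotype in the microglia libraries. Transcripts of myelinating oligodendrocytes, the cells that wrap axons, were higher in KO (13 members, median 0.78, camera adjusted p = 3.53e-06; adjusted p = 0.742 with an estimated correlation), with a median of 0.51 to 0.98 with 1 library left out. The myelin gene Mal stood at 12.9 ± 4.97 FPKM in WT and 34.9 ± 12.8 in KO and the tight junction gene Cldn11 at 9.49 ± 0.273 and 21.8 ± 7.41. Markers of border macrophages, which line vessels and meninges, were lower in KO (12 members, median −0.46, camera adjusted p = 0.00250, and 0.830 with an estimated correlation). Folr2 stood at 7.67 FPKM in WT and 2.46 in KO. The scavenger receptor gene Stab1, which overlaps Nt5dc2 on the other strand and is uncertain, stood at 763 ± 276 FPKM in WT and 485 ± 44.1 in KO. In WT, Stab1 was above the median microglia marker (552 FPKM), so its fall need not be one of other cells. Monocyte markers had a median of −0.62 (9 members, camera adjusted p = 0.0319; adjusted p = 0.830 with an estimated correlation), with the chemokine receptor gene Ccr2 at 2.82 and 0.646 FPKM and the adhesion gene Cd44 at 9.80 and 3.96. Neutrophil and granule markers had a median of −0.74 (11 members, camera adjusted p = 0.0164; adjusted p = 0.742 with an estimated correlation), with S100a8 at 105 and 36.5 FPKM and Retnlg at 12.5 and 3.54. No member of these 4 lists passed limma's test over all genes or adjusted over the list alone, and 7, 1, 2 and 2 members, in that order, had an unadjusted p under 0.05. The border macrophage call was lost without WT library 1 (median −0.25, camera adjusted p = 0.247), the monocyte call without WT library 1 (median −0.071, 0.615) or KO library 3 (median −0.38, 0.130), and the neutrophil call without WT library 1 (median −0.77, 0.152), WT library 3 (median −0.74, 0.0690) or KO library 3 (median −0.50, 0.0657). With 1 library left out the medians ran from −0.71 to −0.25 for border macrophage, from −0.996 to −0.071 for monocyte and from −1.27 to −0.50 for neutrophil markers. Removing the trend with GC content and length also ended the monocyte call (camera adjusted p = 0.0782).

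Transcripts encoded by the mitochondrial genome were lower in KO microglia (35 members, median −0.92, camera adjusted p = 2.65e-17; adjusted p = 0.586 with an estimated correlation), and 21 of them had an unadjusted p under 0.05. The 13 protein-coding members alone had a median of −0.81 (adjusted p = 3.84e-09; 0.742 with an estimated correlation). For mt-Ti, a transfer RNA gene that overlaps mt-Nd1, WT held 1416 ± 281 FPKM and KO 650.2 ± 219. For mt-Td the WT libraries held 474, 122 and 1137 FPKM and KO library 1 held 64.9, while KO libraries 2 and 3 were listed at 0. Genes of cytosolic ribosomal proteins differed by a median of −0.081 (81 members, camera adjusted p = 0.0203; 0.830 with an estimated correlation), which became 0.070 after quantile normalisation, and Rps20 stood at 563 FPKM in WT and 419.6 in KO and Rps21 at 608 and 429. The nuclear genes of oxidative phosphorylation differed by a median of −0.039 (77 members, camera adjusted p = 0.0344; 0.830 with an estimated correlation), with Ndufa6 at 45.9 and 19.9 FPKM and Ndufs4 at 19.1 and 10.4. The ribosomal call was lost without KO library 1 (camera adjusted p = 0.266), WT library 1 (median 0.015, 0.889) or WT library 2 (0.259), and the oxidative phosphorylation call without KO library 1 (0.0921), KO library 2 (0.0860), WT library 1 (0.592) or WT library 2 (0.127). With 1 library left out the medians ran from −0.25 to 0.015 for the ribosomal and from −0.22 to −0.028 for the oxidative phosphorylation list. Adjusted over the list alone, 0 members of these 3 lists passed in limma, against 21, 4 and 7 at an unadjusted p under 0.05.

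The other 21 lists tested in microglia did not pass in camera (adjusted p from 0.0869 to 0.946). Phagocytosis receptors and engulfment machinery had a median of 0.11, and 0 of its 40 members had an unadjusted p under 0.05 in limma. Lysosome genes stood at 0.11, homeostatic microglia genes at 0.10, microglia markers at 0.051, disease-associated or axon-tract-associated microglia genes at 0.029 with a test direction of lower in KO, complement at −0.14, the type I interferon response at 0.21, cell cycle at 0.14 and cholesterol synthesis at 0.26. IL-1 family receptors, ligands and adaptors stood at −0.11, antigen presentation at −0.11 (0.020 after quantile normalisation), reactive astrocyte genes at −0.26, astrocyte markers at 0.19, astrocyte maturation at 0.16, astrocyte synapse-regulating factors at −0.065 and genes near Il33 at −0.066. Markers of neurons stood at −0.29, of oligodendrocyte precursors at −0.17, of endothelial and mural cells at −0.095 with a test direction of higher in KO, of fibroblasts and meninges at −0.40, and sex-linked genes at 0.60 with a mean of −0.47. Adjusted over the list alone, single members fell in 3 of the lists that did not pass or were too small to test. These were H2-K1, an antigen-presenting molecule (193 to 113 FPKM), Cxcl10 among the reactive astrocyte genes, and Rora, a nuclear receptor listed with lymphocyte markers (3.81 to 1.61 FPKM). The lists of lymphocyte and mast cell, ependymal, Schwann cell and erythroid markers had under 5 tested members, and the medians of the 3 with any were −0.51, −0.49 and −0.20 for lymphocyte, Schwann cell and erythroid markers.

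Across all 15890 genes tested in microglia, 13 passed the limma threshold, 9 higher and 4 lower in KO, and 1264 had an unadjusted p under 0.05. The 13 became 48 without KO library 1, 23 without KO library 2, 33 without KO library 3 and 27 without WT library 3. Of the 13, 11 were small RNA genes, and 11 were listed at 0 in every library of one genotype. The KO libraries 1 to 3 held 639, 167 and 97.5 FPKM of Mir7674, 60.4, 69.9 and 81.4 of Mir1956, 54.4, 89.4 and 25.1 of Mir872, 25.1, 68.3 and 34.6 of Mir339 and 16.3, 12.4 and 29.1 of Mir7082, all listed at 0 in the 3 WT libraries. Mir8094 stood at 20.2, 26.2 and 38.3 FPKM in KO and near 0 in WT. Snord107 (54.7, 56.1 and 59.2 FPKM in the WT libraries) and Filip1l (19.6, 17.2 and 21.7) were listed at 0 in all 3 KO libraries, and so was the predicted microRNA gene Gm23424, the last of the 4 lower genes, chosen after its values were seen. The microRNAs lie inside longer genes (Nup214, with Fam78a on the other strand, Eif4e, Ift74, 3110082I17Rik, Raver1 with ENSMUSG00000111497, and Ddx39b, in the order named), Snord107 lies inside Gm38393, and Filip1l overlaps Cmss1 on the other strand, so reads of either gene may count for the other and these values are uncertain. The groups did not overlap for 2525 genes (15.9%), where chance gives 10% on average. Genes move together, so this share can differ much between splits, and it was not counted for the other splits. The Nfkbia call was lost without KO library 1 (limma adjusted p = 0.0507), KO library 2 (0.0696), WT library 1 (0.0648) or WT library 2 (0.0782), with an adjusted p from 0.000857 to 0.229 over all alternatives. The Mir7674 call was lost without KO library 2 (0.0902) or WT library 1 (0.122), 2 (0.125) or 3 (0.103), and the Mir339 call without WT library 1 (0.0648), 2 (0.0782) or 3 (0.0529). The Mir872 call was lost without KO library 1 (0.0579) or WT library 1 (0.0911), 2 (0.0953) or 3 (0.0743), and the Mir7082 call without KO library 1 (0.0538) or WT library 1 (0.0787), 2 (0.0849) or 3 (0.0635).

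The sex of the mice is not stated, and in microglia Xist, the transcript that silences an X chromosome in females, stood at 268 and 283 FPKM in WT libraries 1 and 2 and below 1 in WT library 3 and all KO libraries. With Xist as a covariate, added after the data were seen, the difference rests on WT library 3 alone among the WT. Most calls were then lower in KO, while most calls of the main fit were higher. The NF-kB list then had a median of −0.85 (camera adjusted p = 9.43e-06), while border macrophage markers turned to 0.063 (0.575), monocyte markers to 0.21 (0.789), oxidative phosphorylation to 0.11 (0.789) and ribosomal proteins to 0.17 (0.00670). Over all alternatives the adjusted p of the NF-kB list ran from 1.51e-11 to 0.586.

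The authors' deposited table for microglia, chosen on these same samples and so no independent evidence, lists 483 genes, 277 higher in WT and 206 higher in KO. Of its 413 genes tested here, 409 had the same sign (99.03%, exact binomial 95% interval 97.5 to 99.7), 302 had an unadjusted p under 0.05 and 1, Nfkbia, passed. Nfkbia leads the authors' deposited table with mean normalised counts of 9445 in WT and 1725 in KO (the authors' DESeq2 adjusted p = 1.96e-37). In the authors' deposited table Cxcl10 stood at 1886 in WT and 482 in KO, Cxcl2 at 1047 and 218, and the predicted gene Gm4297 at 321 and 10.3. Higher in KO in the authors' deposited table were Atg9a, which encodes an autophagy membrane protein, at 356 in WT and 801 in KO, the zinc finger gene Zfp574 at 349 and 859 and the antisense transcript Gm15564 at 6950.2 and 13705. Gm15564 overlaps Parp9 and Kpna1 on the other strand and Atg9a overlaps Ankzf1, so both are uncertain. The authors' deposited table holds 12 of the 39 tested NF-kB genes, all higher in WT, where 1.01 would be there by chance (Fisher's exact test, adjusted p = 5.04e-09), and 9 of the 34 dissociation genes, 8 of them higher in WT (adjusted p = 2.19e-06). Fisher's test counts genes as independent, while genes of a list can move together in the same libraries. These p therefore do not measure the spread between animals. That deposited table holds 0 of the 11 small RNA genes called here by limma.

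The comparison of KO with WT astrocytes asked what else differed in the sorted population that held Il33 in WT. Il33 was 1 of 3 genes past the limma threshold, in a fit that found 5% of genes changed by a log2 difference of 1 in simulated data. Il33 differed by −5.55 on the log2(FPKM + 1) scale (SE 0.35, limma adjusted p = 0.0129). The long non-coding 2610307P16Rik (chromosome 13, 28460034 to 28885620) held 12.1, 19.2 and 8.10 FPKM in the WT libraries and 0, 0.169, 0.0793 and 0.612 in the KO libraries, without passing (log2 difference −3.52, limma adjusted p = 0.125). Ide, which encodes a metalloprotease that degrades insulin (chromosome 19, 37268743 to 37337852), stood at 124 ± 19.4 FPKM in WT and 219 ± 19.2 in KO (log2 difference 0.84, limma adjusted p = 0.921).

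Of 13397 genes tested in astrocytes, 3 passed the limma threshold, 1 higher and 2 lower in KO, and 561 had an unadjusted p under 0.05. The groups did not overlap for 627 genes (4.68%), where chance gives 5.71% on average. The other 2 calls were named after their values were seen. Gm25025, a predicted microRNA gene, was listed at 0 in all KO libraries and held 21.5, 15.5 and 21.2 FPKM in WT, and ENSMUSG00000080661, which has no symbol in the annotation used here, held 45.4, 117, 31.0 and 25.5 FPKM in KO and was listed at 0 in WT (limma adjusted p = 0.0139 for both). Further genes with small p that did not pass were Mir762, inside Bcl7c on the other strand and so uncertain, at 81.7, 131, 59.5 and 562 FPKM in KO and listed at 0 in WT (limma adjusted p = 0.0960), and the apolipoprotein gene Apoa2, at 2.85, 3.67, 4.32 and 3.03 FPKM in KO and listed at 0 in WT. Lower in KO without passing were Apip (60.9 and 25.7 FPKM), an enzyme of methionine salvage, and Bdp1 (23.5 and 9.89), a transcription factor of RNA polymerase III. The Il33 call itself was lost without KO library 2 (log2 difference −5.71, limma adjusted p = 0.136), WT library 1 (−5.56, 0.0688) or WT library 3 (−5.71, 0.138), with an adjusted p from 0.000186 to 0.299 over all alternatives. The count of genes in limma was 0 without KO library 2 or WT library 3 (826 and 824 at an unadjusted p under 0.05), 1 without WT library 1, 6 without KO library 1 or KO library 4 and 8 without WT library 2.

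Among the lists, markers of oligodendrocyte precursors were higher in KO astrocytes (9 members, median 0.62, camera adjusted p = 0.0317; adjusted p = 0.880 with an estimated correlation). Tnr, an extracellular matrix gene, stood at 5.12 ± 2.32 FPKM in WT and 9.92 ± 3.63 in KO, and Gpr17, a receptor gene of maturing precursors that overlaps Lims2 on the other strand and is uncertain, at 8.12 ± 0.838 and 15.5 ± 5.83. Adjusted over the list alone 0 members passed in limma, and 2 had an unadjusted p under 0.05. The call was lost without KO library 2 (median 0.53, adjusted p = 0.101), KO library 4 (0.46, 0.156), WT library 2 (0.30, 0.246) or WT library 3 (0.53, 0.0919). The genes near Il33 on chromosome 19 had a median of −0.16 (20 members, camera adjusted p = 0.0317; adjusted p = 0.880 with an estimated correlation), and without Il33 the adjusted p was 0.134. Only Il33 passed in that list, adjusted over the list alone or over all genes, and its neighbour Uhrf2 stood at 15.1 ± 4.21 FPKM in WT and 8.93 ± 2.61 in KO. That call was also lost without KO library 4 (adjusted p = 0.0732) or WT library 2 (0.234), and the median ran from −0.28 to −0.14 with 1 library left out.

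The other 28 lists tested in astrocytes did not pass in camera (adjusted p from 0.0560 to 0.979). Astrocyte maturation had a median of −0.097, astrocyte markers −0.087, reactive astrocyte genes −0.11, astrocyte synapse-regulating factors −0.038 and IL-1 family genes −0.097. In the last 2 lists only Il33 passed, adjusted over the list alone or over all genes, and the next members were the matrix gene Gpc6 (33.8 and 26.0 FPKM in WT and KO) and the kinase adaptor gene Tab3 (1.58 and 8.42). NF-kB targets stood at 0.17 over 16 tested members (camera adjusted p = 0.469). Medians were −0.071 for phagocytosis, with a mean of 0.042, −0.011 for complement, −0.057 for lysosome, −0.077 for cholesterol synthesis, 0.16 for the interferon response, −0.15 for antigen presentation and −0.032 for dissociation genes. Neuron markers stood at 0.57, myelinating oligodendrocyte markers at 0.081, endothelial and mural markers at −0.33, fibroblast and meningeal markers at 0.58, Schwann cell markers at 0.23, erythroid markers at 0.34, ribosomal proteins at 0.089, oxidative phosphorylation at 0.034 and sex-linked genes at −0.48. Under quantile normalisation the median changed sign for disease-associated or axon-tract-associated microglia genes (−0.016 to 0.022), cell cycle (0.015 to −0.060), microglia markers (0.0043 to −0.029), monocyte markers (0.070 to −0.085) and the mitochondrially encoded genes (−0.096 to 0.076). Of these, the disease-associated list had a mean of 0.11 and a test direction of higher in KO, against its median. Homeostatic microglia genes had a median of −0.0035 and a mean of 0.014. The lists of border macrophage, lymphocyte and mast cell, and ependymal markers had under 5 tested members, with medians of 0.33, −0.45 and 0.090, and no neutrophil marker was tested.

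The authors' deposited table for astrocytes, made from these same samples, lists 10 genes, 6 higher in WT and 4 higher in KO. All 9 that were tested here had the same sign (exact binomial 95% interval 66.4 to 100%), and 1, Il33, passed. The authors' deposited table gives mean normalised counts for Il33 of 8729.8 in WT and 115 in KO (the authors' DESeq2 adjusted p = 8.33e-27). Also higher in WT in the authors' deposited table were the transcription factor gene Mecom (470.5 and 146), 2610307P16Rik (191 and 3.91), the kinase subunit gene Pik3r6 (57.3 and 1.57), the glycine receptor gene Glra1 (207 and 22.8) and the centrosomal gene Cep164 (497 and 181). Higher in KO in the authors' deposited table were the actin regulator gene Coro1a (3.29 and 94.7), Ankrd16 (29.8 and 177), C130036L24Rik (17.7 and 114) and Ide (10710.3 and 15267). Coro1a, a gene of blood cells and microglia that overlaps Bola2, stood at 117 ± 26.5 FPKM in WT microglia against 0.211 ± 0.275 in WT astrocytes. The KO astrocyte libraries held 6.23, 1.41, 3.96 and 1.90 FPKM. The median microglia marker was not higher in KO astrocytes (3.59 FPKM in WT and 2.78 in KO), and the source of the Coro1a reads was not tested.

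The interaction of genotype with cell type asked whether the difference between KO and WT was the same in both. Il33 fell in astrocytes and stood at 1.26 FPKM or below in every microglia library, and its interaction, microglia minus astrocytes, was 5.10 on the log2 scale (SE 0.51, limma adjusted p = 0.00177). That call was lost with a pseudocount of 0.1 (4.91, adjusted p = 0.467). A gene near 0 in one cell type cannot fall there, so where it fell in the other its interaction mostly restates that fall. The lists were therefore tested again, after the data were seen, among the 11447 genes with a mean of at least 1 FPKM in both. Of the 37 NF-kB members in the joint fit, 16 were among these, and their median interaction was −0.62 (camera adjusted p = 0.000101; 0.1 with an estimated correlation). Their median difference was −0.41 in microglia and 0.17 in astrocytes, and 4 of the 16 had an unadjusted p under 0.05 for the interaction. The mitochondrially encoded list had a median interaction of −0.87 (35 members, camera adjusted p = 2.04e-10) and the myelinating oligodendrocyte list 0.76 (13 members, 0.00114). Also past the threshold were oligodendrocyte precursor markers (−0.71, camera adjusted p = 0.0112), neuron markers (−1.35, 0.0151), fibroblast and meningeal markers (−0.98, 0.0331), cholesterol synthesis (0.18, 0.0487) and oxidative phosphorylation (−0.15, 0.0151). Each of these 7 lists had an adjusted p of 0.570 with an estimated correlation. Ribosomal proteins passed too (−0.21, camera adjusted p = 0.000163; 0.663 with an estimated correlation), and their median over the joint fit was −0.080 after quantile normalisation. The dissociation list did not pass (median −0.23, camera adjusted p = 0.229). Border macrophage and neutrophil markers had 3 and 0 members above the filter in both and were not tested in this way. Over the joint fit both passed (median −0.51, camera adjusted p = 0.0243, and −0.92, 0.00823; adjusted p = 0.658 and 0.620 with an estimated correlation), which mostly restates their fall in microglia. Of 16258 genes, 23 passed in limma, 14 higher and 9 lower, and 19 were small RNA genes. Among the calls with a symbol other than a Gm number, the largest interactions were those of Mir7674 (7.78), Mir1956 (7.76) and Mir872 (5.67), and of Mir762 (−7.11), Snord107 (−5.85) and Filip1l (−4.44), all uncertain since each overlaps another gene. The interaction of Mir1956 ran from 6.15 to 8.33 with 1 library left out. Mir7674, Mir872 and Snord107 were listed at 0 in every astrocyte library and Mir762 in every microglia library, so these 4 interactions are the difference in the other cell type. Among the genes above the filter in both, 2 passed in limma, Gm25025 and ENSMUSG00000080661. The 23 became 15 without WT astrocytes 2, 75, 45 and 35 without KO microglia 1, 2 and 3, and 60, 57 and 46 without WT microglia 1, 2 and 3. At an unadjusted p under 0.05 there were 1076. Il1rl1 (−0.045, limma adjusted p = 0.994) and Il1rap (0.47, 0.836) did not pass.

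The comparison of WT microglia with WT astrocytes described what each sort held. Microglial genes filled one population and astrocyte genes the other. The purinergic receptor gene P2ry12 stood at 1412 ± 296 FPKM in microglia and 4.01 ± 2.02 in astrocytes (SD, n = 3 each), Tmem119 at 395 ± 163 and 0.670 ± 0.743, and the fractalkine receptor gene Cx3cr1 at 658 ± 71.0 and 1.52 ± 0.590. In astrocytes the folate enzyme gene Aldh1l1 stood at 91.3 ± 12.7 FPKM against 0.206 ± 0.111 in microglia, the water channel gene Aqp4 at 1333 ± 286 against 6.16 ± 1.12 and the glutamate transporter gene Slc1a3 at 387 ± 45.6 against 23.4 ± 8.15. All 20 tested microglia markers were higher in microglia and 19 of 20 astrocyte markers in astrocytes, by limma. The exception, the glutamate transporter gene Slc1a2, was listed at 0 in WT astrocytes 1 and KO astrocytes 3, while WT astrocytes 2 and 3 held 3996 and 1631 FPKM and KO astrocytes 1, 2 and 4 held 3352, 1697 and 3048. The mitochondrial gene mt-Co1 was likewise listed at 0 in 6 of the 7 astrocyte libraries and at 15627 FPKM in WT astrocytes 3, so a 0 in this table can be a failed estimate.

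In all, 8717 of 16258 genes differed between WT microglia and WT astrocytes in limma, 4737 higher in microglia and 3980 higher in astrocytes. After quantile normalisation the split was 3764 and 4930, and the median of all genes moved from 0.21 to −0.065, a shift that left the direction of each list named here unaltered. Cholesterol synthesis genes were higher in astrocytes (22 of 23), as were astrocyte maturation genes (27 of 28), astrocyte synapse-regulating factors (21 of 27) and nuclear genes of oxidative phosphorylation (75 of 79). Cell cycle genes were higher in microglia (34 of 38), as were NF-kB genes (33 of 37), antigen presentation (18 of 21), the complement system (12 of 18) and ribosomal proteins (64 of 81). Relative to the marker level of each population, the median astrocyte marker reached 0.974% in WT microglia and the median microglia marker 0.751% in WT astrocytes. Border macrophage markers reached 7.18% of the microglial level, with Stab1 at 763 and Pf4 at 178 FPKM. Stab1 was thus above the median microglia marker (552 FPKM). Myelinating oligodendrocyte markers reached 1.89% in microglia and 13.6% in astrocytes, where Mbp stood at 3552 ± 779 FPKM. Oligodendrocyte precursor markers reached 1.62% and 1.70%. Olig1 at 380.3 ± 55.9 FPKM and Olig2 at 70.8 ± 8.08 were the most abundant of them in astrocytes, where the list median was 8.12. Neuron and erythroid markers reached 1.09% and 1.05% in astrocytes, with Snap25 at 38.9 ± 22.4, Nefl at 18.6 ± 8.80, Bpgm at 91.8 and Hbb-bs at 42.4 ± 50.4 FPKM.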

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

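The tests of the causes of the lower NF-kB transcripts, of GC content and length as the whole cause and of the small RNA genes were chosen only after the result was seen. The GC content difference, the test without WT microglia 3 and the counts of other splits were set beforehand, but not the count of splits by age.

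The interaction term in limma passed for 7 of the named genes. Il33 fell in KO astrocytes, and Snord107 and Filip1l were listed at 0 in every KO microglia library. Each was near 0 in the other cell type, where it cannot fall. A listed 0 can be a failed estimate, so the fall of Snord107 and Filip1l is uncertain. Mir7674, Mir872 and Snord107 were listed at 0 in all 7 astrocyte libraries and Mir762 in all 6 microglia libraries. Filip1l stood at 0.280 FPKM or below in the astrocytes and Il33 at 1.26 or below in the microglia. The interaction, microglia minus astrocytes, was 5.10 for Il33, 7.78 for Mir7674, 7.76 for Mir1956, 5.67 for Mir872, −7.11 for Mir762, −5.85 for Snord107 and −4.44 for Filip1l. That of Mir1956 ran from 6.15 to 8.33 with 1 library left out. The Il33 call was lost with a pseudocount of 0.1 (4.91, adjusted p = 0.467). The call of Mir1956 was lost without KO astrocytes 1 (adjusted p = 0.0617), 3 (0.0723) or 4 (0.0664), WT astrocytes 1 (0.0530) or 2 (0.0611), KO microglia 2 (0.0606) or 3 (0.0676) or WT microglia 3 (0.0578), and that of Mir762 without WT astrocytes 2 (0.0501). In KO astrocytes, library 4 held 562 FPKM of Mir762 where the others held 59.5 to 131 FPKM, a gap of 0.857 of the range, above Dixon's limit for 4 libraries. This was 1 of 21 genes checked, and chance gives about 1 in 20 groups such a gap.

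The lower NF-kB transcripts in KO microglia were set against other sources of these transcripts. The FPKM lost in KO over the neutrophil markers was 0.109 of that lost over the NF-kB genes (0.0786 to 0.144 with each library left out). Fewer neutrophils cannot be told apart from a change within microglia, since this ratio decides only with a neutrophil profile that no table gives, and the neutrophil markers themselves had a median of −0.74 in KO. The same holds for fewer border macrophages and monocytes, whose loss came to 0.411 of the NF-kB loss and ranged from 0.105 without WT microglia 1 to 0.833 without WT microglia 3. These markers lost 449 FPKM in all, and Stab1 alone went from 763 FPKM in WT to 485 in KO. The median border macrophage marker stood at 39.7 FPKM in WT microglia, so the ratio leans mostly on Stab1 and does not measure a loss of cells. Induction during dissociation stays open, since the dissociation genes without shared members also had a median of −0.26 (camera adjusted p = 0.00311; 0.742 with an estimated correlation), as it would if WT cells had been stressed longer. With Xist as a covariate the list had a median of −0.85, but this leaves 1 WT library of the KO class, so the sex of the mice cannot be told apart from genotype either, and the loss of Il33 itself, the biological explanation in the design, stays open beside them.

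The genes of the authors' deposited table for microglia differed in GC content by direction. The median GC was 46.8% for genes higher in WT and 54.1% for genes higher in KO, a difference of −7.28 points (permutation p = 1e-05, the smallest that 100000 resamples give). The permutation shuffled directions over genes as if these were independent, so its p does not measure the spread between animals. Removing a trend with GC content and length within each library left 102% of the median difference of genes higher in WT. For genes higher in KO it left 92.5%, while the correlation of all genes with GC fell from 0.108 to 0.0127. As the genes were chosen on these 6 libraries and the trend over all genes was weak, they tend to keep their difference under this removal. The test therefore cannot tell how far a GC effect, as part or whole of the cause, sets their direction. Without WT microglia 3, 87.0% of the median difference of genes higher in WT was kept, the lowest share over the 6 libraries left out in turn (up to 109%). This met the bound set beforehand, but that bound was wrong, since genes chosen on all 6 libraries tend to keep their difference. So it stays open how far WT microglia 3 carries it. A GC trend between libraries that may add to the difference stays open, as does a biological difference between genotypes in which genes respond, which was not tested.

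The small RNA genes among the microglial calls may reflect short genes (median exonic length 92 bases) whose FPKM is 0 in one group. Without the genes listed at 0 in any library, which by construction takes out genes of that kind, 1 of the 11 small RNA calls was left, and the 2 calls left in all were Nfkbia and Mir8094. Reads of the host genes are a further explanation that could not be tested without strand or reads.

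For the microglia, the 10 splits of 6 libraries are too few for a share under 0.05. As many genes came from 3 of the 10 splits (13 in the real one, 17 in the highest other) and as many lists from 4 (9 and 16). For the WT cell types the 10 splits are also too few (1 with as many genes, 8717 in the real one and 3 in the highest other). In astrocytes chance cannot be excluded, since 16 of 35 splits gave as many genes as the real 3 and the highest other gave 68, and 29 of 35 gave as many lists as the real 2 (highest other 7). The 5 splits that put KO library 2 and WT library 3, both of day 9, in the group of 3 gave 47 to 68 genes. With age in the fit these compare 1 library with 4, so they say little about the real split. Of the 20 splits with 1 day 9 library in each group, as in the real one, 4 gave as many genes (highest other 6) and 16 as many lists (highest other 7), and 20 are too few for a share under 0.05. With the day 12 libraries alone the real split gave 0 genes in limma, and 736 at an unadjusted p under 0.05. For the interaction 23 of 100 splits drawn gave as many genes as the real 23, with 163 in the highest other. Of the 64 drawn with 1 day 9 library in each astrocyte group, 7 did, with 29 in the highest other, so chance cannot be excluded for that count.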

How the results depend on the processing

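Tests of protein-coding and long non-coding genes only, without genes listed at 0, with a sex covariate and with GC content and length removed were added after the data were seen. Over the 10 answers to a comparison, 115 of 165 alternatives were the same, 29 weaker, 21 stronger and 0 reversed. Most of these answers are counts or shares, where the same means a value near the main one and no direction can reverse. For Il33 and the 72 named genes and lists, the same means the direction and the side of the threshold. For those 72 the numbers were 1254 of 1375, 95, 10 and 16. Where no cause follows from fewer genes or libraries in the fit, the cause was not tested. The 13 genes in microglia became 25 with a pseudocount of 0.1, 7 with no filter, 37 with all libraries in one fit, 2 among protein-coding and long non-coding genes, 2 without genes listed at 0 and 278 with the sex covariate, and 18 to 48 with 1 library left out (48 without KO library 1, 23 without KO library 2, 33 without KO library 3 and 27 without WT library 3). The 9 microglial lists became 0 with an estimated correlation and 6 to 13 with 1 library left out. The 3 genes in astrocytes became 5 with a pseudocount of 0.1, 0 in limma with no filter (847 at an unadjusted p under 0.05), 7 with all libraries in one fit, 0 in limma with day 12 libraries alone (736 unadjusted) and 1 each among protein-coding and long non-coding genes, without genes listed at 0 and with the sex covariate, and 0 to 8 with 1 library left out (in limma 0 without KO library 2 or WT library 3, with 826 and 824 unadjusted, 1 without WT library 1, 6 without KO library 1 or 4 and 8 without WT library 2). Il33 in astrocytes kept its direction throughout and lost its call with no filter (−5.55, limma adjusted p = 0.138), with day 12 libraries alone (−5.71, 0.0698) and without single libraries (−5.76 to −5.36). The 2 astrocyte lists became 1 with no age term, 0 with an estimated correlation, 0 with GC content and length removed and 0 to 5 with 1 library left out (5 without KO library 3, 4 without WT library 1, 1 without WT library 2 and 0 without KO library 4). The 23 genes of the interaction became 37 with no filter, 13 at 5 FPKM, 2 among protein-coding and long non-coding genes and 0 in limma without genes listed at 0 (769 at an unadjusted p under 0.05), and 15 to 75 with 1 library left out (15 without WT astrocytes 2, and for the microglia 75, 45 and 35 without KO 1, 2 and 3 and 60, 57 and 46 without WT 1, 2 and 3). The 8717 genes between cell types ranged from 7965 to 8722 with 1 library left out.

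Directions reversed for the ribosomal list in microglia (0.070 by quantile normalisation, 0.17 with the sex covariate), for Il1rl1 in microglia (0.32 with the sex covariate, −0.45 to 0.41 with 1 library left out), for the border macrophage list (0.063) and the oxidative phosphorylation list (0.11) with the sex covariate, for Il1rap in astrocytes (−0.028 by quantile normalisation, −0.071 with array weights, −0.068 with the block, −0.074 to 0.24 with 1 library left out) and for Il1rl1 in the interaction (0.023 with a pseudocount of 0.1, −0.43 to 0.43 with 1 library left out). The median of the monocyte list also became 0.21 with the sex covariate. The libraries were taken to share only a replicate number and not to be paired, since no pair reached a correlation of 0.1, and the deviations of libraries with the same number correlated at 0.028, 0.012 and 0.023 in microglia and at 0.018, −0.079 and −0.018 in astrocytes. All 3 microglia pairs correlated best with their own number, a hint from the data and not from the design, and 0 of the 3 astrocyte pairs did. With the number as a block, 3 genes were called in microglia and, in place of age, 0 in astrocytes in limma (394 at an unadjusted p under 0.05), with Il33 at −5.46 (adjusted p = 0.299), while Nfkbia had an adjusted p of 0.229. Depth is known only as relative values, which are lower for the astrocytes, and limits what low genes can show.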

Other observations

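The tests of this part were chosen after the result was seen, apart from the interaction of the whole NF-kB list, whose bound was set before its result.

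Agtrap, which encodes a protein that binds the angiotensin receptor, was higher in KO libraries of both cell types. It was chosen after its values were seen and passed in neither. The KO microglia held 16.3, 10.04 and 13.7 FPKM and the WT microglia 3.11, 3.03 and 2.11 (limma log2 difference 1.92, adjusted p = 0.162). The KO astrocytes held 8.23, 15.8, 12.2 and 20.8 FPKM and the WT astrocytes 4.65, 2.18 and 3.31 (1.78, adjusted p = 0.921). The authors' deposited tables do not list it.

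The sexes of the libraries differ in ways the labels do not give. WT microglia 1 and 2 held 268 and 283 FPKM of Xist together with 2.62 and 3.86 FPKM of the Y-linked gene Ddx3y, while WT microglia 3 and the 3 KO microglia libraries held under 1 FPKM of Xist and 7.45, 6.73, 6.53 and 7.94 FPKM of Ddx3y. Among the astrocytes, KO libraries 3 and 4 and WT library 2 held under 0.1 FPKM of Ddx3y and 10.1, 32.4 and 32.9 FPKM of Xist, and KO libraries 1 and 2 and WT libraries 1 and 3 held 8.31, 5.89, 9.98 and 7.73 FPKM of Ddx3y.

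A hypothesis was that the NF-kB genes depend on Il33 in the cells that carry its receptor and not in the sorted astrocytes, where Il33 was found. The interaction of the whole list had a median of −0.72, but only 16 of its 37 members pass the filter in both cell types, and the others cannot fall in astrocytes, which largely fixes its sign. Among the 16 members above the filter in both cell types the median interaction was −0.62 (camera adjusted p = 0.000101; 0.1 with an estimated correlation), so the difference may be larger in microglia. In astrocytes these 16 members had a median difference of 0.17 (camera adjusted p = 0.469), while Nfkbia stood at 30.4 FPKM in WT and 17.5 in KO, with libraries that overlap (exact permutation p = 0.0857). Lower stress of KO microglia during dissociation would give the same sign, so the test does not separate the causes.

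Ide was higher in KO in both of the authors' deposited tables, with mean normalised counts of 1592 in WT and 3034 in KO microglia (the authors' adjusted p = 0.0196) and 10710.3 and 15267 in astrocytes (0.0340). It lies 7.31 megabases from Il33 on chromosome 19, so DNA of another strain linked to the Il33 allele is a candidate cause. The test counted genes of the authors' tables within 10 megabases of Il33, a window set when the position of Ide was known. For microglia it found 2 of 94 genes, Ide and Ptar1, where chance gives 2.44 (Fisher's exact test p = 1, odds ratio 0.814, 95% interval 0.0968 to 3.04). For astrocytes it found 1 of 83 genes, Ide, where chance gives 0.0496 (Fisher's exact test p = 0.0485, adjusted over both tests 0.0970). A count this small cannot tell whether Ide, or Ptar1 with the opposite direction, owes its difference to linked DNA.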
